A study of Mus musculus with 6 samples.

How the data were processed

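RNA levels were measured with 6 Affymetrix gene-level mouse arrays, 3 from wild-type mice and 3 from sanroque mice, with a different sample on each array. Per the labels, the samples were CD8+ T cells with low surface CD44, sorted by flow cytometry from spleen and lymph node suspensions of 10-week-old C57BL/6 mice. Sanroque mice carry a homozygous point mutation of Roquin, the RNA-binding protein encoded by Rc3h1. The labels call the samples biological replicates.

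The authors deposited 1 linear intensity per probe set and array, between 9.56 and 31996, made from biotin-labelled cRNA per the labels' protocols. Partek is the tool named in the submitters' processing notes, with no role given. The background correction, summarization and normalization are not given in the sources used here. The scale was read from the values. Median intensities per array were 53.6, 55.4 and 56.0 in wild type replicates 1 to 3 and 56.9, 56.1 and 54.9 in sanroque replicates 1 to 3. The largest gap between arrays at any compared quantile was 0.14 on the log2 scale, so the values were put on log2 with no further normalization. The number of arrays limits the precision. A gene near the low end of the scale holds mostly background, so folds that start there understate the change. Xist, for example, read between 4.02 and 4.17 in the 5 arrays where it was low.

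Of the 35399 probe sets, 21789 had exactly 1 gene symbol in the platform annotation, 1621 had several and 11989 were not listed. Symbols were updated through the gene table of assembly GRCm38.p6, which matched 19856 of the 19938 genes, and no coordinates were taken from it. For each of the 999 genes with several probe sets, the probe set with the highest mean over the 6 arrays was used. Among called genes, 74 had a further probe set, which went the opposite way in 4, and in 0 of these did the further probe set pass in the opposite direction.

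Genes were compared with limma's lmFit and eBayes (limma 3.58.1, R 4.3.3), two-sided, with no filter on dim genes, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all 19938 genes. Log2 folds are sanroque minus wild type, printed with the standard error of limma's moderated fit, and group levels are means with SD over 3 arrays. The median log2 fold of all genes was -0.03. The design, the alternatives, the rule for named genes and 15 biology lists and 11 cell-origin lists were fixed before the data were examined. Lists were tested with limma's camera at the preset inter-gene correlation of 0.01, adjusted within each of these list families, and again with an estimated correlation and with fry. The count of members past the threshold is given over all genes and adjusted over the list alone.

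Named genes were Rc3h1, Rc3h2, Cd44, Ifng, Icos and Cd8a, then the 10 called genes with the largest log2 fold in each direction whose groups did not overlap, leaving out provisional symbols. To these were added up to 4 called members of each biology list with the largest absolute log2 fold, or the 2 with the smallest p where none was called. Each cell-origin list gave its 2 members with the highest mean level and the 1 with the smallest p. Other genes appear where they were singled out after their values were seen.

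On 20 simulated data sets of this size, with 200 of 19938 genes changed, limma recovered 60.7% of changes of 0.5 on the log2 scale, 97.9% of changes of 1 and 99.9% of changes of 2, and 5.00% of calls were false. The noise was drawn as independent normal values with limma's moderated SDs and without outlying arrays, so recovery in the real data may be lower. In these independent simulated genes camera called the shifted list in 20 of 20 data sets and 7 of 500 tests of unshifted lists. Real genes are correlated. In the 9 other splits of the 6 real arrays into 3 and 3, camera at the preset correlation called 2 to 13 biology lists, against 12 in the split by genotype. With an estimated correlation it called 0 in each of the 9 and 1 by genotype. Each of the 9 mixes the genotypes unevenly, so its calls can hold part of the genotype difference.

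Alternatives covered the choice of probe set, filters on dim genes, quantile normalization, median centring, other variance models, array weights, one-way ANOVA per gene without moderation, a fold minimum of 1.5, the replicate number as a block, other list tests and leaving out each array. Added after seeing the data were a fit with a score of other cell types as a covariate and a fit without sanroque replicate 1 and wild type replicate 2. The score of an array was the mean of its B cell and myeloid list medians, centred over the arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.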

Results

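The data compared RNA levels in CD44-low CD8+ T cells of sanroque and wild-type mice, with 3 arrays per genotype. CD44 is an adhesion receptor that T cells raise after activation, so a CD44-low gate takes mostly cells of naive surface type. The comparison asks how the transcript levels of these sorted cells differ when Roquin, which binds and represses mRNAs such as Icos, carries the sanroque mutation.

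The mutated gene itself was measured first. Rc3h1 read 10.00 ± 0.10 in wild type and 10.15 ± 0.16 in sanroque (log2 intensity, mean ± SD, n = 3 each), with a log2 fold of 0.14 ± 0.10 (limma, Benjamini-Hochberg adjusted p = 0.564). The arrays read 9.93, 10.11 and 9.97 in wild type and 9.98, 10.17 and 10.30 in sanroque. Another, dimmer Rc3h1 probe set gave a log2 fold of -0.24. The allele is a point mutation, so this level does not check the labels. Its paralog Rc3h2 had a log2 fold of 0.15 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 0.385).

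The largest rises among named genes in sanroque cells were in the cytotoxic effector genes Gzma, Ccl5, Klrg1 and Gzmb. Next came the neutrophil genes Ngp, S100a8 and Lcn2, ahead of the effector gene Klrc1. Gzma and Gzmb, proteases of cytotoxic granules, were 25.4-fold and 19.7-fold higher. The chemokine gene Ccl5 was 23.4-fold higher, and the receptor genes Klrg1 and Klrc1 were 20.1-fold and 15.9-fold higher. Cd8a, which encodes a coreceptor chain of these cells, read 13.02 ± 0.03 in wild type and 13.00 ± 0.02 in sanroque (SD, n = 3 each). Transcripts that mark B cells and myeloid cells were also higher in all 3 sanroque arrays, including the neutrophil genes Ngp (17.3-fold), S100a8 (16.7-fold), Lcn2 (16.6-fold), S100a9 (15.3-fold) and Ltf (12.7-fold).

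In all, 1151 of 19938 genes passed limma's test, 650 higher and 501 lower in sanroque. The rises were larger than the falls. At least a 2-fold change was seen in 246 of the higher and 8 of the lower genes, and at least a 4-fold change in 65 and 2. The 2 genes lower by at least 4-fold were the provisional A530021J07Rik, which the naming rule leaves out, at a log2 fold of -2.22 ± 0.17, and Slc6a19, a neutral amino acid transporter, at -2.10 ± 0.25. Leaving out provisional symbols, Rcn3 at -1.26 ± 0.19 came next. Gstk1 (-1.16), Tmie (-1.13), Rida (-1.12), Tdgf1 (-1.06), Fam71b (-0.99), Ephx1 (-0.97), Atp1b1 (-0.91) and Sh3pxd2a (-0.91) followed. Another Sh3pxd2a probe set, with a mean level of 7.40 against 7.41, gave a log2 fold of -0.33 and did not pass. The 3 values of each group did not overlap in 4519 genes, or 22.7%, where chance gives 10%. The count was 218 without wild type replicate 1, 489 without wild type replicate 2, 603 without sanroque replicate 1 and 392 without sanroque replicate 2. It was 353 without both arrays in doubt (described with the cell-origin markers), 0 with a score of other cell types as a covariate, and 4 by a per-gene test without moderation, while array weights raised it to 4733. The 501 lower calls numbered 22 and 91 without wild type replicates 1 and 2, and 148 and 55 without sanroque replicates 1 and 2. They numbered 454 without wild type replicate 3 and 728 without sanroque replicate 3.

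**Figure D1:**
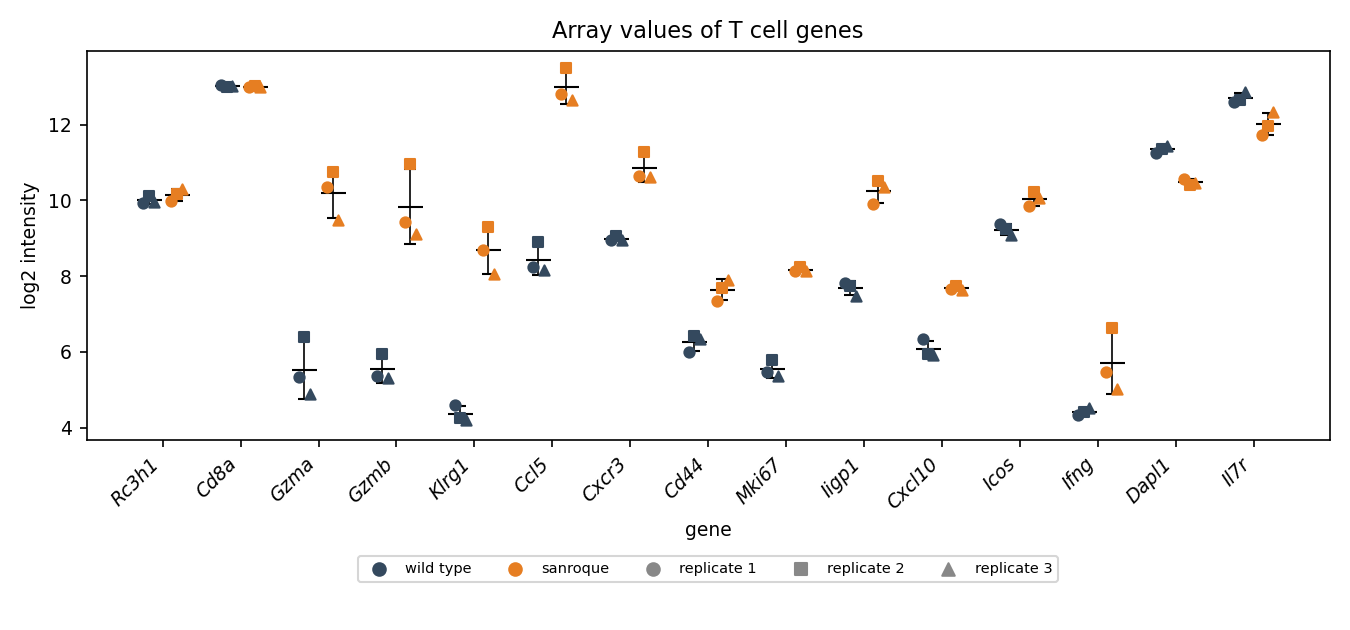
Log2 intensity of 15 genes on each array, with wild type in dark blue and sanroque in orange and a symbol for each replicate. Horizontal lines are means and error bars are SD over 3 arrays. Cd8a lies at 13.02 and 13.00 in the 2 groups, while Gzma, Gzmb, Klrg1 and Ccl5 do not overlap between groups.

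Among 25 cytotoxic effector genes, 15 rose, 1 fell and 9 did not pass over all genes, and 20 rose and 2 fell when adjusted over the list alone. Gzma rose from 5.53 ± 0.78 to 10.20 ± 0.65 (SD, n = 3 each; log2 fold 4.67 ± 0.44, limma, Benjamini-Hochberg adjusted p = 0.00354). Ccl5 had a log2 fold of 4.55 ± 0.27, Klrg1 of 4.33 ± 0.29 and Gzmb of 4.30 ± 0.45. Klrd1, whose product pairs with NKG2 receptors, fell by 0.48. Ifng, which encodes interferon gamma, was higher in each sanroque array than in any wild-type array but did not pass (log2 fold 1.28 ± 0.36, limma, Benjamini-Hochberg adjusted p = 0.0957). On the same arrays the medians of the myeloid and B cell marker lists were higher by 1.56 and 1.54 in sanroque. Leaving out each array in turn left 11 to 17 effector genes higher. Sanroque replicate 2 had an effector list median level of 9.30, against 8.26 and 8.30 in the other sanroque arrays. It also had the highest stress and dissociation median (9.48). Of that list's named genes Jun was highest there, but Hspa8 and Hsp90aa1 were highest in sanroque replicate 3. Without sanroque replicate 2 the effector list's median log2 fold was 1.81. The list had a median log2 fold of 1.96 (limma camera, Benjamini-Hochberg adjusted p = 6.5e-21), with an adjusted p = 0.119 with an estimated correlation. At the preset correlation camera also called 2 to 13 biology lists in the 9 splits of the arrays that mix genotypes, and at an estimated correlation 0.

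Of 18 central and virtual memory genes, 10 rose and 0 fell over all genes, and 15 rose when adjusted over the list alone. Anxa1 rose by 3.36 ± 0.47 on the log2 scale, Il18rap by 3.32 ± 0.36, S100a6 by 2.30 ± 0.33 and Ccr2 by 2.23 ± 0.21. Cd44, the gene of the sort marker, rose from 6.25 ± 0.23 to 7.65 ± 0.28 (SD, n = 3 each; 2.63-fold, limma, Benjamini-Hochberg adjusted p = 0.00669). Sanroque replicate 2 had a memory list median level of 9.98, against 9.33 and 9.18 in the other sanroque arrays, and without it the median log2 fold was 1.15. Leaving out wild type replicate 1 left 6 memory genes higher. Several of these genes, such as Anxa1 and S100a6, are also expressed by myeloid cells, whose list had a median log2 fold of 1.56. The list's camera adjusted p was 1.4e-14 and its median log2 fold 1.34 (limma, Benjamini-Hochberg), with an adjusted p = 0.119 with an estimated correlation.

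Most of the 18 measured naive and quiescence genes did not pass: 2 fell, 1 rose and 15 stayed above the adjusted p threshold, with the same counts of 2 and 1 when adjusted over the list alone. Dapl1 fell by 0.89 on the log2 scale and Il7r, the receptor chain for the survival cytokine interleukin 7, fell by 0.69. Bcl2, an anti-apoptotic gene, rose by 0.38 ± 0.07. Ccr7, a lymph node homing receptor gene, had a log2 fold of -0.28 and Lef1, a transcription factor of naive T cells, of -0.11, and neither passed. Leaving out any single array other than sanroque replicate 3 left 1 of these genes lower, and 0 were higher without any of the wild-type arrays or sanroque replicate 1. The list's camera adjusted p was 0.227 (limma, Benjamini-Hochberg).

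Cell cycle genes rose as a group. Of 29 measured, 17 rose and 0 fell over all genes, and 25 rose and 1 fell when adjusted over the list alone. Mki67, a marker of cycling cells, rose from 5.54 ± 0.22 to 8.17 ± 0.05 (SD, n = 3 each; 6.17-fold, limma, Benjamini-Hochberg adjusted p = 0.000999). Top2a rose by 2.31 ± 0.12, Ccna2 by 2.26 ± 0.15 and Ccnb2 by 1.53 ± 0.14 on the log2 scale. Leaving out wild type replicate 1 left 9 higher and sanroque replicate 2 left 11. The B cell and myeloid marker lists, higher by medians of 1.54 and 1.56, moved the same way. This was the only biology list past the threshold under both correlations (limma camera, Benjamini-Hochberg adjusted p = 1.1e-26, and 0.0251 with an estimated correlation).

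Interferon gamma response genes rose in 12 of 20 cases with 0 falling, and 15 rose when adjusted over the list alone. The immunity-related GTPase gene Iigp1 rose by 2.58 ± 0.17 on the log2 scale, the chemokine genes Cxcl10 and Cxcl9 by 1.61 ± 0.12 and 1.59 ± 0.12, and Ciita, the activator of MHC class II genes, by 1.47 ± 0.19. The list had a median log2 fold of 0.67 (limma camera, Benjamini-Hochberg adjusted p = 6.7e-20), with an adjusted p = 0.119 with an estimated correlation. Ciita is also expressed by B cells, and Cxcl9 and Cxcl10 by myeloid cells, whose lists had medians of 1.54 and 1.56. The count of 12 was 6 without wild type replicate 1, 7 without wild type replicate 2 and 8 without sanroque replicate 2. Of 25 type I interferon response genes 5 rose and 0 fell, as when adjusted over the list alone, led by Oasl2 (1.23 ± 0.14), Stat2 (0.79 ± 0.13), Zbp1 (0.70 ± 0.08) and Ifih1 (0.67 ± 0.15). Leaving out any single array left 2 or 3 higher. Their median log2 fold was 0.18 (limma camera, Benjamini-Hochberg adjusted p = 3.7e-07), with an adjusted p = 0.254 with an estimated correlation and 0.108 by fry.

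Among 13 measured mRNAs reported as Roquin targets, 4 rose, 0 fell and 9 did not pass over all genes, and 6 rose when adjusted over the list alone. Icos, a costimulatory receptor gene, rose from 9.23 ± 0.14 to 10.04 ± 0.19 (SD, n = 3 each; 1.76-fold, limma, Benjamini-Hochberg adjusted p = 0.0142). The transcription factor gene Irf4 rose by 1.09 ± 0.13, Ptgs2 by 0.43 ± 0.09 and Nfkbiz by 0.40 ± 0.09 on the log2 scale. Tnfrsf4, which encodes OX40, had a log2 fold of -0.10 ± 0.11 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.781). On the same arrays the B cell, plasma cell and myeloid marker lists were higher by medians of 1.54, 0.47 and 1.56, and Irf4 is also a gene of B and plasma cells and Ptgs2 of myeloid cells. Leaving out each array in turn left 2 to 4 Roquin target genes higher. The list's camera adjusted p was 0.00015 (limma, Benjamini-Hochberg), with an adjusted p = 0.119 with an estimated correlation. Of 25 genes of the mRNA decay machinery, 0 rose and Cnot8, a deadenylase subunit, fell by 0.49, and 0 passed in either direction when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0291 with the list higher, and adjusted p = 0.391 with an estimated correlation and 0.391 by fry). Cnot8 did not pass when any array other than wild type replicate 3 or sanroque replicate 3 was left out.

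Of 13 inhibitory receptor genes 3 rose and 0 fell, and 8 rose when adjusted over the list alone. The 3 were Entpd1 (log2 fold 3.30 ± 0.29), Ctla4 (2.13 ± 0.35) and Cd244a (1.56 ± 0.16), and the list's camera adjusted p was 6.1e-06 (limma, Benjamini-Hochberg), with an adjusted p = 0.119 with an estimated correlation. Of 23 chemokine receptor and integrin genes 10 rose and 0 fell, and 12 rose and 2 fell when adjusted over the list alone, with Cx3cr1 (3.13 ± 0.27), Itgax (1.96 ± 0.31) and Cxcr3 (1.87 ± 0.17) among them. Their camera adjusted p was 6.1e-08 (limma, Benjamini-Hochberg), with an adjusted p = 0.0971 with an estimated correlation. Of 11 follicular helper genes, Cxcr5 (1.40 ± 0.23), Icos and Maf (0.76 ± 0.13) rose and 0 fell, and 5 rose when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 3.2e-05, and adjusted p = 0.0971 with an estimated correlation). Cxcr5 is also a B cell gene and Itgax a myeloid gene, and the lists of these cells had medians of 1.54 and 1.56 on the same arrays. Sanroque replicate 2 stood apart for the inhibitory receptors, with a list median level of 9.20 against 7.08 and 7.58 in the other sanroque arrays. It also had the highest median of the stress and dissociation list (9.48), though not the highest Hspa8 or Hsp90aa1. Leaving it out took the median log2 fold of the inhibitory receptors from 1.05 to 0.69. Inhibitory receptor genes called higher numbered 5 without sanroque replicate 1 and 6 without sanroque replicate 2. Without wild type replicate 1, 2 inhibitory receptor genes, 5 chemokine receptor and integrin genes and 1 follicular helper gene rose.

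Of 20 early T cell receptor response genes, Rgs1 (1.69 ± 0.35), Il2ra (0.65 ± 0.13) and Nr4a1 rose while Tnfrsf18 and Cd69 fell by 0.54 and 0.53, and 5 rose and 3 fell when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0889). Leaving out any single array left 0 to 2 of these higher and 0 or 1 lower, with 0 and 0 without wild type replicate 1. Of 12 BCL2 family genes, the anti-apoptotic Bcl2 and Bcl2l1 (0.36 ± 0.06) rose, and so did the pro-apoptotic Pmaip1 (0.65 ± 0.13), with 0 falling and 4 rising when adjusted over the list alone. The count of 3 was 0 without any of the wild-type arrays or sanroque replicate 2, 1 without sanroque replicate 1 and 2 without sanroque replicate 3. Their camera adjusted p was 0.0030 (limma, Benjamini-Hochberg), with an adjusted p = 0.119 with an estimated correlation and 0.0738 by fry. Of 12 glycolysis genes, Hk2 alone rose, by 0.58 ± 0.13, and 1 rose when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0630). Hk2 did not pass when any array other than sanroque replicate 1 was left out. Of 21 cytoplasmic ribosomal protein genes 0 passed, also when adjusted over the list alone, with a median log2 fold of -0.11, -0.65 ± 0.22 for Rpl12 and -0.27 ± 0.09 for Rpl10 (limma camera, Benjamini-Hochberg adjusted p = 0.0072 with the list lower, and adjusted p = 0.119 with an estimated correlation).

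**Figure D2:**
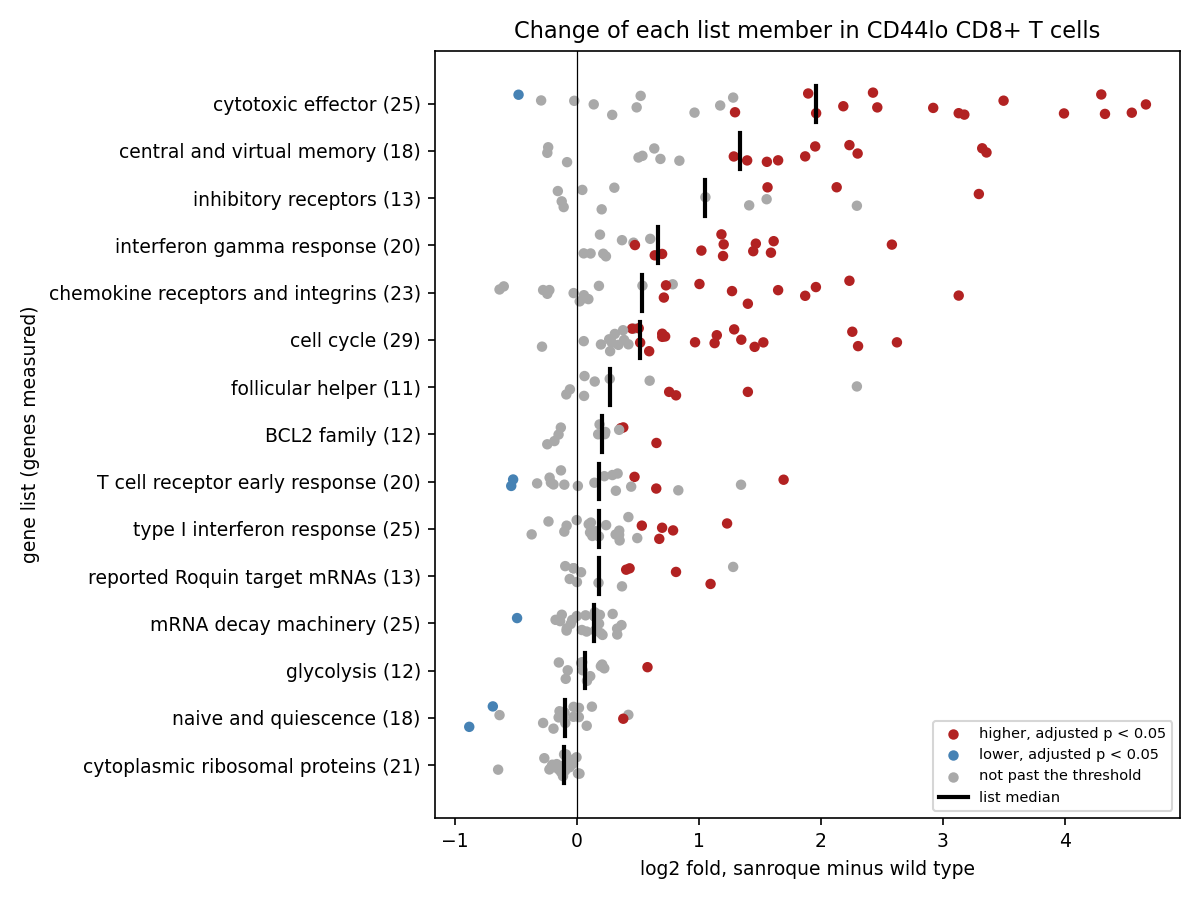
Log2 fold, sanroque minus wild type, of each measured member of the 15 biology lists, with the number measured in brackets. Red points were higher and blue points lower at adjusted p below 0.05, grey points did not pass, and black bars are list medians, which run from 1.96 for cytotoxic effector genes to -0.11 for cytoplasmic ribosomal protein genes.

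Markers of cells outside the gate moved with genotype. Of 15 monocyte, macrophage and neutrophil genes 12 rose and 0 fell, and 13 rose when adjusted over the list alone. The median log2 fold was 1.56, and this was the only cell-origin list past the threshold under both correlations (limma camera, Benjamini-Hochberg adjusted p = 2.8e-20, and 0.0469 with an estimated correlation). Lyz2 rose by 3.12 ± 0.36 and Fcer1g by 2.16 ± 0.15, while Ctss, also expressed in T cells, had a log2 fold of -0.03. Of 13 B cell genes 8 rose and 0 fell, and 13 rose when adjusted over the list alone, including Cd74 (2.08 ± 0.39), Cd22 (1.81 ± 0.24) and H2-Ab1 (1.79 ± 0.37). The count of 8 was 12 without wild type replicate 2, 0 without wild type replicate 1 and 2 without each of the other arrays. Their median was 1.54 (limma camera, Benjamini-Hochberg adjusted p = 3.4e-14, and adjusted p = 0.158 with an estimated correlation). The plasma cell genes Jchain (3.28 ± 0.60), Mzb1 (1.81 ± 0.21) and Xbp1 (0.75 ± 0.16) rose among 6 measured, as did 3 when adjusted over the list alone, and 0 fell (limma camera, Benjamini-Hochberg adjusted p = 0.00082, and adjusted p = 0.0860 with an estimated correlation). The count of 3 was 1 without wild type replicate 1 or 3 or sanroque replicate 2, and 2 without each other array.

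Of 7 CD4 T cell genes, Ctla4, Ikzf2 (1.07 ± 0.19) and Zbtb7b (0.80 ± 0.18) rose, and 5 rose when adjusted over the list alone, while Cd4 itself had a log2 fold of 0.95 ± 0.25 and did not pass (limma camera, Benjamini-Hochberg adjusted p = 3.0e-05, and adjusted p = 0.0860 with an estimated correlation). The count of 3 was 0 without wild type replicate 1 or 3, 1 without wild type replicate 2 or sanroque replicate 1, and 2 without sanroque replicate 2. Of 8 NK cell genes, Fcgr3 (0.89 ± 0.08), also a myeloid gene, and Klre1 (0.83 ± 0.11) rose, and 3 rose when adjusted over the list alone. Ncr1, Adgrg3 and Adamts14 had log2 folds of -0.12, -0.09 and 0.23 (limma camera of the list, Benjamini-Hochberg adjusted p = 0.0021, and adjusted p = 0.0860 with an estimated correlation). Of 9 dendritic cell genes Itgax alone rose, also when adjusted over the list alone, and Cst3 and Ccr9 had log2 folds of 0.36 and -0.64 (limma camera, Benjamini-Hochberg adjusted p = 0.0920, and adjusted p = 0.0080 by fry). Of 10 CD8 T cell identity genes, Cd3d, Lat and Cd247 fell by 0.52, 0.41 and 0.33 and 0 rose, with 3 lower and 1 higher when adjusted over the list alone, and Cd3g had a log2 fold of -0.14 (limma camera, Benjamini-Hochberg adjusted p = 0.0311 with the list lower, and adjusted p = 0.279 with an estimated correlation). The count of 3 lower was 0 to 2 when any single array was left out. Itgax did not pass without wild type replicate 1 or 2. Ctla4 is also in the inhibitory receptor list and Itgax in the chemokine receptor and integrin list. Their rises need not come from cells outside the gate.

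In 4 further cell-origin lists 0 genes passed limma's test, over all genes or adjusted over the list alone. The erythroid and platelet list had 6 measured members, with 0.63 for Slc4a1 and -0.09 for Itga2b (limma camera, Benjamini-Hochberg adjusted p = 0.195). The gamma delta T cell list had 3, with -0.01 for Sox13 and 0.09 for Zbtb16 (limma camera, Benjamini-Hochberg adjusted p = 0.602). The stress and dissociation list had 11, with 0.19 for Hspa8, 0.14 for Hsp90aa1 and 1.34 for Jun (limma camera, Benjamini-Hochberg adjusted p = 0.147), and the sex-linked list had 4 (limma camera, Benjamini-Hochberg adjusted p = 0.616).

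Individual arrays stood apart in these markers. Sanroque replicate 1 read 11.20 for Xist, transcribed from the inactive X of females, against 4.02 to 4.17 in the other 5 arrays, and 4.26 for the Y-linked Eif2s3y against 9.77 to 10.19. Uty read 3.92 there. The labels give no sex, but these values read as female RNA in sanroque replicate 1 and male RNA in the other 5 arrays. By these genes the sanroque group was mixed in sex and the wild-type group was not. Wild type replicate 2 had more B cell and myeloid transcript than the other wild-type arrays, with Ms4a1 at 8.03 against 6.17 and 6.41 and Lyz2 at 8.56 against 7.30 and 6.98. Without these 2 arrays, a fit added after seeing the data, 12 effector, 8 memory, 11 cell cycle, 11 interferon gamma, 12 B cell and 11 myeloid genes were called higher by limma. The same fit called 2 Roquin target, 1 type I interferon, 1 CD4 T cell and 2 plasma cell genes higher.

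**Figure D3:**
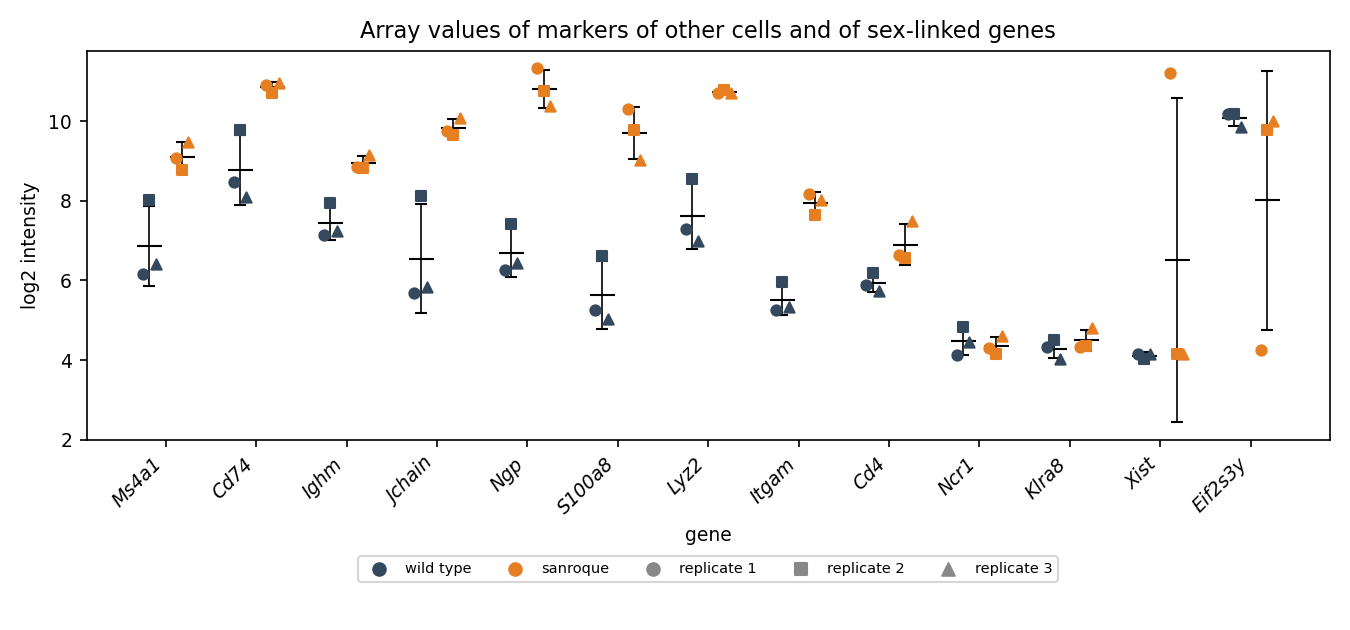
Log2 intensity of B cell, plasma cell, myeloid, CD4, NK and sex-linked genes on each array, with wild type in dark blue and sanroque in orange and a symbol for each replicate. Horizontal lines are means and error bars are SD over 3 arrays. Sanroque replicate 1 lies apart for Xist (11.20) and Eif2s3y (4.26), and wild type replicate 2 is the highest wild-type array for Ms4a1 (8.03) and Lyz2 (8.56).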

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

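The tests of carried-over cells, of a lower CD8 share, of the array with high Xist, of the other-cell score and of a general interferon response were chosen after the results were seen. The counts over other splits were set out before theirs were. Bootstrap intervals here resampled genes, not mice. Genes of a list are not independent, so these intervals do not measure the spread between mice.

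Probe sets outside the gene test also differed between genotypes, a signal in data the comparison did not use. Of those not listed in the annotation, 20 were higher and 1 lower in sanroque (limma, Benjamini-Hochberg over these probe sets, with 1093 at an unadjusted p below 0.05), and of those with several symbols 19 were higher and 0 lower, with 292 at an unadjusted p below 0.05.

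B cell and myeloid transcripts were higher in all 3 sanroque arrays, although the CD8 gate would remove such cells. Whether carried-over B cells are part of the source stays open. Deviations of B cell genes from their group means had a mean pairwise correlation of 0.88, above 100% of 10000 random lists matched on level. Without wild type replicate 2 it was 0.46, at the 99.9th percentile. Genes regulated together would exceed random lists too. Named B cell genes also varied more in wild type. The SDs of Cd74, H2-Ab1 and Cd22 were 0.88, 0.84 and 0.53 there, against 0.13, 0.15 and 0.06 in sanroque. So the correlation reflects mostly differences between wild-type arrays and does not decide the source of the sanroque rise. For carried-over myeloid cells the correlation was 0.14 (98.0th percentile) but 0.03 (72.0th percentile) without wild type replicate 2, so this stays open. A lower CD8 share that raises other types alike stays open for these 2 lists, with myeloid folds above B cell folds by 0.41 (bootstrap 95% interval -0.25 to 1.11). Medians were 0.22, 0.10, 0.04 and 0.03 in the NK, dendritic, erythroid and platelet, and gamma delta lists. Their 26 genes rose less than B cell and myeloid genes by a mean log2 fold of 1.57 (interval 1.16 to 1.99). But these lists were taken up after their folds were seen, and set against the lists with the highest medians. The CD4 and plasma cell lists, with medians of 0.80 and 0.47, were left out. So the gap does not decide whether every type rose alike. Also, 18 of the 26 lay at or below the median level of genes in wild type, where a small share might not show. H2-Ab1, Cd74, Ngp and Lyz2 had mean levels of 11.27, 10.86, 10.82 and 10.74 in sanroque, 0 members of either list were in another list, 11 of 13 B cell and 9 of 15 myeloid genes lay above the median of genes in wild type, and a change of these genes within sanroque T cells was not tested.

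Cytotoxic effector genes had the highest median rise of the 15 biology lists. Carried-over NK cells, which the CD8 gate would mostly remove, stay open as a source. Effector genes exceeded NK genes by a mean log2 fold of 1.67 (bootstrap over genes, 95% interval 0.97 to 2.37). Of the 8 NK genes, 6 lay at or below the median level of genes in wild type, where a small NK share might not show. The 15 effector genes that started as low exceeded those 6 by 2.10 (1.32 to 2.89). But the fold that carried-over cells give a gene depends on its level in those cells, which was not measured. So these gaps do not decide the question. Among 23 Klr receptor genes, a family chosen after the data were seen, 6 rose and 1 fell. Klra2 and Klra3, outside the NK list, rose by 1.16 ± 0.17 and 0.80 ± 0.10, so an NK share stays open. The array with high Xist is argued against as the source, since the effector list's median was 1.96 without it (limma fry, Benjamini-Hochberg adjusted p = 0.0197). A shared other-cell source cannot be told apart from genotype, because the other-cell score correlated with genotype at 0.967. At equal score the median was 2.16 but limma fry gave a Benjamini-Hochberg adjusted p = 0.599. A CD8 T cell effect of the mutation remains a hypothesis. Cd44, the gene of the sort marker, was 2.63-fold higher in sanroque. The share of CD8 T cells with high CD44 in the samples is not known from these data. So a change within CD44-low cells cannot be told apart from a change in which CD8 T cells were present.

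Interferon gamma response genes rose more than type I response genes. The difference in mean log2 fold was 0.60 (permutation of list membership, p = 0.00018 with 100000 permutations, over genes that are not independent). So the lists did not rise alike on these arrays. This does not decide on a general interferon response, since Ciita, Cxcl9 and Cxcl10 are also expressed by B cells or myeloid cells. Other-cell content cannot be told apart from genotype here, with a limma fry Benjamini-Hochberg adjusted p = 0.599 and a median of 0.45 at equal score against 0.67 without the score.

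The split by genotype gave 1151 genes, and the highest of the other 9 splits gave 0, so 1 of the 10 splits gave as many. For biology lists at the preset correlation the split by genotype gave 12 and the highest other split 13, so 2 of the 10 splits gave as many, and for cell-origin lists the counts were 6 and 4, so 1 of 10 gave as many. With 10 splits no share under 0.05 can be reached. Each of the other 9 splits also mixes the genotypes unevenly, so its list calls can hold part of the genotype difference. These counts are therefore not a clean reference for chance.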

How the results depend on the processing

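The fit with an other-cell score as a covariate and the fit without sanroque replicate 1 and wild type replicate 2 were chosen after seeing the data, and all other settings before. The count of 1151 genes (650 higher, 501 lower) stayed within 1.5 times with the mean of probe sets, either filter on dim genes, quantile normalization, median centring and either intensity trend. It moved to 566 (425 and 141) with probe sets tested singly, 591 with a fold minimum of 1.5 (458 and 133), 4733 with array weights (1998 and 2735) and 353 without both arrays in doubt (326 and 27, 325 shared with the 1151). ANOVA without moderation called 4 (0 and 4), and the score covariate 0 (0 and 0). Leaving out each array gave 218 to 1315 genes, 196 to 587 higher and 22 to 728 lower. With the replicate number as a block 301 genes passed (271 and 30). The numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.05, -0.16 and -0.36, and 0 arrays correlated best with their own number. The causes were not tested. Of 12 biology lists 1 passed with an estimated correlation and 6 with the covariate, mRNA decay in the opposite direction. Of 6 cell-origin lists 1 and 1 passed, the latter the B cell list, itself part of the score, in the opposite direction. With fry 9 and 7 passed, the dendritic cell list among them only there. Leaving out each array gave 11 to 14 biology and 5 to 7 cell-origin lists.

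Of 71 called named genes, 44 stayed called with the block, 65 with median centring, 0 with ANOVA, 0 with the covariate, 45 without both arrays in doubt and 39 to 62 when leaving out each array, and 0 reversed except 8 with the covariate. These were Ifih1 (log2 fold -0.057), Cxcr5 (-0.67), H2-Ab1 (-1.92), Cd74 (-1.84), Cd22 (-0.52), Xbp1 (-0.12), Jchain (-2.69) and Lyz2 (-0.45). H2-Ab1, Cd74, Cd22 and Lyz2 are members of the lists that make up the score, so their reversal cannot be read as a result. In this setting the score also nearly equals genotype. Genes that had not passed also turned there: Rc3h1 (-0.29), Rc3h2 (-0.23), Cd8a (0.055), Tnfrsf4 (0.030), Cst3 (-0.17), Itga2b (0.43), Sox13 (0.46) and Hsp90aa1 (-0.29). So did the directions of the lists for type I interferon (camera adjusted p = 0.313, limma, Benjamini-Hochberg), Roquin targets (0.943), glycolysis (0.866), mRNA decay (0.0179), B cell (2.0e-11), plasma cell (0.876) and dendritic cell (0.876). The B cell list is part of the score, so its reversal cannot be read as a result either. Rc3h1 turned with the mean of its probe sets (-0.049), and Sox13 (0.026) and Hsp90aa1 (-0.33) with array weights. Without both arrays in doubt Tnfrsf4 (0.014), Ctss (0.011), Zbtb16 (-0.025), Uty (0.27) and the sex-linked list (camera adjusted p = 0.311, limma, Benjamini-Hochberg) turned. Leaving out each array, uncalled folds crossed 0 for Tnfrsf4 (-0.17 to 0.026), Adgrg3 (-0.21 to 0.0064), Ctss (-0.094 to 0.029), Sox13 (-0.054 to 0.042), Zbtb16 (-0.025 to 0.27), Hsp90aa1 (-0.25 to 0.40) and Uty (-2.37 to 0.13), and the sex-linked list turned (camera adjusted p 0.394 to 0.866, limma, Benjamini-Hochberg). Leaving out probe sets by the ending of their names and the check of 3 prime against 5 prime control probe sets were not run, since the names do not carry such endings or controls. Genes near the low end of the scale, such as Il2 and Ncr1, give little room to see a fall.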

Other observations

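The families here were chosen after the data were seen, and the receptor segment test was set out before its result. Of 9 caspase genes, with a median log2 fold of 0.05, the inflammatory Casp1 and Casp4 rose by 2.93 ± 0.27 and 2.27 ± 0.13 on the log2 scale and the executioner Casp6 fell by 0.65. The interferon-induced membrane protein genes Ifitm6 (3.38 ± 0.38), Ifitm3 (3.38 ± 0.46), Ifitm1 (1.49 ± 0.14) and Ifitm2 (0.69 ± 0.11) rose among 7 measured, and 2 of 5 Slamf genes rose, led by Slamf7, a receptor gene of activated lymphocytes, at 2.60 ± 0.26. All 4 measured Fc gamma receptor genes rose, with Fcgr4 at 2.18 ± 0.22 and Fcgr2b at 1.26 ± 0.08. So did 4 of 8 immunoglobulin kappa variable genes, and 4 of 10 Toll-like receptor genes, with Tlr7 at 0.89 ± 0.17 and Tlr9 at 0.65 ± 0.07. Of 7 Lilr and Pir genes 4 rose, with Lilrb4a, an inhibitory receptor gene of myeloid and effector T cells, at 2.81 ± 0.30 and the related Lilr4b at 2.74 ± 0.29. Many of these genes are expressed by B cells or myeloid cells, whose lists had medians of 1.54 and 1.56 on the same arrays, so these rises need not come from the sorted T cells. With an estimated correlation 0 of these families passed, the lowest limma camera Benjamini-Hochberg adjusted p being 0.0823 for Fc gamma receptors.

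Of 43 genes named for mitochondrial complex I subunits and assembly factors, 3 fell and 0 rose. Ndufa9 fell by 0.48, and the median log2 fold was -0.22 (limma camera, Benjamini-Hochberg adjusted p = 1.4e-06, and adjusted p = 0.195 with an estimated correlation). Of 40 proteasome subunit genes 2 fell, Psmd6 by 0.59 and Psmd12 by 0.42, and 0 rose, with a median of -0.16 (limma camera, Benjamini-Hochberg adjusted p = 0.00055, and adjusted p = 0.344 with an estimated correlation). The glutathione transferase genes Gstk1 and Gstp3 fell by 1.16 and 0.49 among 19 measured, and 0 rose (limma camera, Benjamini-Hochberg adjusted p = 0.0210, and adjusted p = 0.131 with an estimated correlation). Over all genes, the 501 calls of a lower level numbered 22 without wild type replicate 1 and 27 without both arrays in doubt.

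Sanroque replicate 2 read highest of the 6 arrays for several genes that did not pass the test, with Pdcd1 at 9.38 against 6.94 and 7.75 in the other sanroque arrays, Tigit at 9.51 against 7.50 and 7.58, Lag3 at 8.15 against 6.49 and 6.64, and Jun at 9.60 against 8.05 and 8.38. The median level of the 11 stress and dissociation genes, which include Jun, was also highest there, at 9.48 against 8.30 and 8.77 in the other sanroque arrays and 8.51 to 8.77 in wild type. Not every member followed: Hspa8 and Hsp90aa1 read 13.38 and 11.75 there, against 13.51 and 12.81 in sanroque replicate 3. Pdcd1, the gene of the PD-1 receptor, had a log2 fold of 2.30 ± 0.54 (limma, Benjamini-Hochberg adjusted p = 0.0576).

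A less even T cell receptor repertoire in sanroque mice may raise the spread of variable segment genes between arrays. The median log2 ratio of SD, sanroque over wild type, was 0.21 over the 5 Trav and Trbv genes above the median level, at the 58.7th percentile of random lists matched on level, which decides nothing with 5 genes. Trbv1 fell by 0.89 (limma, Benjamini-Hochberg adjusted p = 0.0472).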
